A study of Homo sapiens with 6 samples.

How the data were processed

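RNA sequencing of HHL-5 cells, all given free fatty acids, gave 6 libraries in 2 groups of 3, control and ZBED3-OE, with groups and replicate numbers taken from the sample titles. The deposited table has 58735 genes with FPKM per library, coordinates and a gene length. The table names no unit; FPKM is inferred from the values, since each value times the gene length is a whole number of equal steps, so the authors divided whole reads by length. All non-zero values (100%) lay within 0.02 of a whole read, and whole reads per gene were recovered. The denominator the authors used per sample was not a whole number, was 1.0019 to 1.0427 times the reads in listed genes, and followed the samples' median-of-ratios size factors to between -0.456% and 0.342%, so the deposited FPKM are already scaled between samples. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and hg38 were used, with no roles stated. The roles of these builds, the counting tool, its treatment of shared reads and strand, and the annotation are not given in the sources used here. All 58735 gene IDs had the chromosome, start, end and strand of GENCODE 29 on GRCh38, and coordinates are given on that build. Libraries were prepared from total RNA with a TruSeq kit, per the labels.

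Depth was taken as recovered reads in listed genes, 13301041 to 15011425 per library. A single read in a gene of 1 kb is worth 0.0643 to 0.0750 FPKM, which sets the step of the lowest values. Between 25208 and 26439 genes had a value above 0. Within each group, no pair of libraries was a repeat of the other by a chi-square comparison of reads.

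The test was limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, on log2(FPKM + 1), a pseudocount of 1 FPKM. Genes with at least 1 FPKM in at least 3 samples were tested, which left 13656. The model held the group and no other term. Genes past a Benjamini-Hochberg adjusted p of 0.05 are called changed, with no fold minimum. The plan provided for a count test in case of raw counts and for this test in case of FPKM; as the values are FPKM, calls rest on this test, and voom on recovered reads is among the alternatives.

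Gene lists were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 22 lists that had at least 3 tested members, out of 25 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction without comparison to other genes, were run beside it. The 3 lists not tested were lipoprotein assembly and bile acid metabolism, endothelial markers, and macrophage and leukocyte markers. Members were also adjusted over the list alone. The lists of immediate early and heat shock genes and of mitochondrially encoded transcripts were fixed as checks of sample quality, not as pathways. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined.

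Named genes were ZBED3, the 10 genes with the largest log2 fold change in each direction among changed genes with at least 1 FPKM in the higher group, no overlap between groups and a symbol that is not a clone, locus, antisense, microRNA or pseudogene name, and up to 4 changed members of each list with the smallest p, or the member with the smallest p where none passed. One gene that the rule names is not reported here. Levels of CTNNB1, ALB, HNF4A, CEBPA and ZBED3-AS1 were chosen after values were seen.

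The alternatives were pseudocounts of 0.1 and 0.01 FPKM, no filter or a filter at 5 FPKM, a common median, quantile normalization, no intensity trend, replicate number as a block, voom on recovered reads with median-of-ratios scaling, each library left out in turn, and a log2 fold minimum of 1. Added after seeing the data were voom with library totals, a filter of 10 recovered reads, protein-coding genes only, and removal of a loess trend (span 0.5) on GC content and gene length from each library. Bootstrap intervals over list members used 10000 draws at 95%, and that for long non-coding genes 1000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

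The procedure was tested on simulated reads for 13658 genes with 200 changed genes, drawn from the means and depths of these libraries for ZBED3-OE against control. Limma on log2(FPKM + 1) recovered 56% of 50 genes changed 1.5-fold, 90% of 50 changed 2-fold, 96% of 50 changed 3-fold and 100% of 50 changed 4-fold, and 8.54% of its calls were false. Voom recovered 88% of the genes changed 1.5-fold, and 5.22% of its calls were false. The list shifted in the simulation was the only 1 called. The simulation did not test list calls under correlation between genes or under GC trends of single libraries. In the real libraries the estimated correlation was 0.484 for mitochondrially encoded transcripts and 0.414 for glycolysis and hypoxia. How often lists are called falsely in these data is therefore not shown. Recovery was given by fold change and not by read number. The 200 changed genes were drawn only from genes with at least 50 reads on average, so recovery does not speak for genes with few reads. All genes shared the same dispersion, 0.0080, and no library was given a spread of its own. The simulated shares therefore do not show how many calls are recovered or false in the real libraries. No sequence was examined, and no strand or isoform was analysed here.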

Results

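Gene expression was measured by RNA sequencing in HHL-5 cells, an immortalised line of human hepatocytes. All 6 libraries came from cells kept for 24 hours in medium with 750 µM free fatty acids, a treatment used in culture to load hepatocytes with lipid. Of these, 3 were control libraries and 3 came from cells overexpressing ZBED3 (ZBED3-OE), a zinc finger protein known to bind axin in the Wnt pathway. The comparison addresses how gene expression in HHL-5 cells given free fatty acids differs when ZBED3 is overexpressed. No library came from cells without free fatty acids, so no difference can be tied to them. The table held 58735 genes as FPKM. The reads in listed genes, recovered from those values, numbered 14496581, 13426227 and 13301041 in the controls and 14920618, 15011425 and 14195162 in ZBED3-OE.

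Pearson correlations between libraries across genes, which are not independent replicates, ran from 0.967 to 0.981 within control, from 0.979 to 0.983 within ZBED3-OE and from 0.958 to 0.973 between groups. Control 3 stood apart from the other controls: on the first principal component, with 39.6% of the variance, it lay at -1.23, against -24.8 and -19.6 for controls 1 and 2 and 9.0, 22.5 and 14.2 for the ZBED3-OE libraries. Transcripts of the mitochondrial chromosome took 4.21%, 4.27% and 5.10% of reads in the controls and 5.58%, 5.99% and 5.66% in ZBED3-OE. The groups did not overlap, and the smallest two-sided p that an exact permutation test of 3 against 3 samples allows is 0.1. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. How ZBED3 was overexpressed and what the control cells carried are not given in the labels either. Effects of the delivery and of ZBED3 itself therefore cannot be told apart for any gene or list below, the interferon list included.

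ZBED3 itself (ENSG00000132846, chromosome 5, 77072072 to 77087323, minus strand, GRCh38) was listed at 3.88, 4.76 and 4.07 FPKM in the controls and 11.8, 11.1 and 11.3 FPKM in ZBED3-OE, a 2.69-fold difference of the means. In ZBED3-OE, 10 of 25 tested genes of cholesterol synthesis and uptake fell. That list passed as lower (camera, Benjamini-Hochberg adjusted p = 3.8e-10, and 0.039 with an estimated correlation). So did the list for glycolysis and hypoxia, in which 17 of 28 fell, and that for lipid uptake and droplets, in which 4 of 25 fell (camera, Benjamini-Hochberg adjusted p = 3.8e-20 and 0.0014; adjusted p = 0.138 for each with an estimated correlation). PLIN2, the main coat protein of hepatocyte lipid droplets, fell from 16.6 ± 1.12 to 3.70 ± 0.114 FPKM (SD, n = 3), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell from 16.04 ± 3.81 to 2.15 ± 0.424 FPKM. PFKFB4, which makes the allosteric activator of phosphofructokinase, fell from 14.6 ± 1.98 to 4.28 ± 0.861 FPKM. In the other direction, the lists of interferon-stimulated genes and of mitochondrially encoded transcripts passed as higher, with 3 of 21 and 3 of 13 genes passing singly (camera, Benjamini-Hochberg adjusted p = 2.3e-06 and 1.7e-06; adjusted p = 0.065 and adjusted p = 0.246 with an estimated correlation).

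By limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, 553 of 13656 tested genes changed at an adjusted p under 0.05, of which 216 were higher and 337 lower in ZBED3-OE. ZBED3 rose by 1.25 on the log2 scale (SE 0.086, limma, Benjamini-Hochberg adjusted p = 0.0043). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The libraries of the groups did not overlap for 3681 genes, or 27.0% of those tested, where chance gives 10% on average. Genes move together, so a single split can lie far from 10%, and the share was not computed for other splits. All 553 changed genes were among the 3681, which a low p with 3 against 3 samples makes nearly certain. The median log2 fold change over tested genes was -0.0041. Differences of at least 1 on the log2 scale were found in 36 higher and 40 lower genes. Over all genes, 1619 of 13402 changed without control 3 and 2243 of 13647 after removal of a GC and length trend. Counts of list members in these fits are to be read against those totals. With voom on recovered reads scaled by library totals, 53.4% of calls were higher, against 39.1% in the 553.

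**Figure D1:**
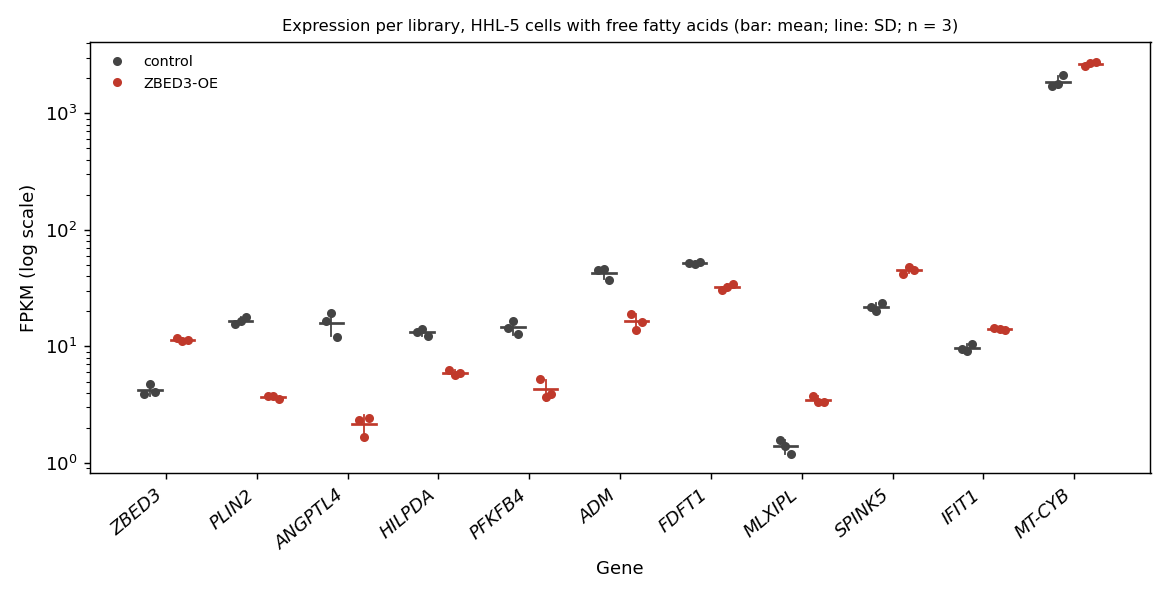
FPKM on a log axis in each of the 6 libraries for 11 named genes, with controls in grey and ZBED3-OE in red; points are libraries, horizontal bars are means and vertical lines are SD (n = 3). For PLIN2, the controls lie between 15.5 and 17.8 FPKM and the ZBED3-OE libraries between 3.57 and 3.77 FPKM.

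Of 25 genes tested in the list for fatty acid uptake, triglyceride synthesis and lipid droplets, 4 fell and none rose (1 higher and 9 lower when adjusted over the list alone). These were PLIN2 (chromosome 9, 19108375 to 19149290), with a log2 fold change of -1.91 (SE 0.077, limma, Benjamini-Hochberg adjusted p = 0.00042), ANGPTL4 (chromosome 19, 8363289 to 8374373) with -2.42, HILPDA with -1.03 and ACSL5 with -0.55. HILPDA, an inhibitor of adipose triglyceride lipase, went from 13.2 ± 0.867 to 5.97 ± 0.352 FPKM, and ACSL5, an acyl-CoA synthetase, from 3.98 ± 0.546 to 2.39 ± 0.0483 FPKM. The list median was -0.090, and the list passed as lower by camera (Benjamini-Hochberg adjusted p = 0.0014; adjusted p = 0.138 with an estimated correlation). The list mean was -0.32, so a few large falls weigh in that result. Without control 3, 7 genes of the list fell and its median was -0.15. With voom on recovered reads or the 5 FPKM filter the median was -0.14. In the same list 2 rose and 10 fell after a GC and length trend was removed from each library. The lists for fatty acid synthesis and fatty acid oxidation did not pass, with camera adjusted p (Benjamini-Hochberg) of 0.709 and 0.752. Among 17 tested genes of fatty acid synthesis, 1 rose and 1 fell, the same numbers as when adjusted over the list alone. MLXIPL, the carbohydrate-responsive transcription factor ChREBP, rose from 1.40 ± 0.194 to 3.48 ± 0.271 FPKM, and ACSS2, which makes acetyl-CoA from acetate, fell from 21.6 ± 0.326 to 12.6 ± 0.556 FPKM. MLXIPL did not pass without control 2, ZBED3-OE 2 or ZBED3-OE 3, and 2 genes of that list fell without control 3. With the GC and length trend removed, 3 rose and 2 fell in the synthesis list, and 3 rose and 6 fell in the oxidation list. Of 28 genes of fatty acid oxidation and ketogenesis, 1 rose and 2 fell, again with the same numbers adjusted over the list alone: DECR1 had a log2 fold change of 0.43, the carnitine carrier SLC25A20 of -0.52 and ACAA2 of -0.44. In the oxidation list, 2 rose and 4 fell without control 3, 0 rose and 1 fell without control 1, and none passed without control 2 or any of the ZBED3-OE libraries.

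Glycolysis and hypoxia formed the list with the smallest camera p. Of its 28 genes, all tested, 17 fell and none rose (24 lower when adjusted over the list alone), and 27 had a log2 fold change under 0. The number that fell was 5 without control 2, 6 without ZBED3-OE 2, 4 without ZBED3-OE 3 and 9 with no filter on low values. The list median was -0.50 (camera, Benjamini-Hochberg adjusted p = 3.8e-20; adjusted p = 0.138 with an estimated correlation, which came to 0.414). Mean deviations of the list on the log2 scale were 0.37, 0.41 and 0.21 in controls 1 to 3 and -0.19, -0.41 and -0.38 in the ZBED3-OE libraries, without overlap between the groups. PFKFB4 had a log2 fold change of -1.57, the vasodilator peptide gene ADM of -1.34, the HIF prolyl hydroxylase EGLN3 of -1.09 and the aldolase ALDOC of -1.05. EGLN3 went from 5.75 ± 0.193 to 2.18 ± 0.305 FPKM and ALDOC from 34.5 ± 2.46 to 16.2 ± 1.93 FPKM.

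Of 25 tested genes of cholesterol synthesis and uptake, 10 fell and none rose (14 lower when adjusted over the list alone), with a list median of -0.38. Without ZBED3-OE 1, 4 fell, and without control 2, ZBED3-OE 2 or ZBED3-OE 3, 0 fell, while the list passed by camera in each of these fits. With no filter on low values, 4 fell. The list passed by camera (Benjamini-Hochberg adjusted p = 3.8e-10). It was the only one of the 11 passing lists to hold with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.039). Estimates for the interferon, NF-kB, p53 and autophagy lists were 0.0038, -0.019, -0.013 and -0.0079, all below the preset 0.01. These lists still did not pass with them, so a larger correlation does not account for the loss of their calls. FDFT1, squalene synthase, went from 52.0 ± 1.05 to 32.3 ± 2.10 FPKM and DHCR7, the last enzyme of one branch of the pathway, from 24.7 ± 1.73 to 14.7 ± 1.07 FPKM. Log2 fold changes were -0.67 for FDFT1, -0.71 for DHCR7, -0.69 for the sterol dehydrogenase NSDHL and -0.66 for the thiolase ACAT2. In the list for gluconeogenesis and insulin signalling, which did not pass (camera, Benjamini-Hochberg adjusted p = 0.709), 1 of 17 tested genes fell, also when adjusted over the list alone. This was IGFBP1, a liver-secreted binding protein of insulin-like growth factors, at 117 ± 10.8 FPKM in control and 52.7 ± 5.57 FPKM in ZBED3-OE; without control 3, 3 genes fell, and after a GC and length trend was removed, 2 rose and 2 fell.

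The lists that passed as higher were interferon response and mitochondrially encoded transcripts. The latter was fixed as a check of sample quality, and a difference in sample quality between the groups was not tested. Of 21 tested interferon genes, 3 rose and none fell (10 higher and 1 lower when adjusted over the list alone), and the list median was 0.32 (camera, Benjamini-Hochberg adjusted p = 2.3e-06; adjusted p = 0.065 with an estimated correlation). The number that rose was 1 without control 1, 9 without control 3, where 1 fell, and 0 without control 2 or any of the ZBED3-OE libraries. With voom 9 rose, and after a GC and length trend was removed, 12 rose and 1 fell. With no filter on low values, 0 rose and the list median was 0.21. OASL rose from 27.4 ± 1.996 to 42.3 ± 2.63 FPKM, IFIT1 from 9.72 ± 0.780 to 14.2 ± 0.222 FPKM and HERC5, an ISG15 ligase, from 15.6 ± 1.61 to 22.8 ± 1.06 FPKM. Of the 13 mitochondrially encoded mRNAs, 3 rose and none fell (9 higher when adjusted over the list alone), with a list median of 0.35 (camera, Benjamini-Hochberg adjusted p = 1.7e-06; adjusted p = 0.246 with an estimated correlation). These were MT-CYB at 0.52, MT-CO2 at 0.51 and MT-ATP6 at 0.59 on the log2 scale. Without control 3, 10 rose, and without any of the other libraries, 0 rose. With voom on recovered reads 6 rose, and with no filter on low values 0 rose. Quantile normalization, which gives equal ranks equal values, lowered the list median to 0.15 (camera, Benjamini-Hochberg adjusted p = 0.0049). It left MT-CYB and MT-CO2 at 0 and MT-ATP6 at 0.11 (limma, Benjamini-Hochberg adjusted p = 0.514 for MT-ATP6). With no filter on low values the list no longer passed (camera, Benjamini-Hochberg adjusted p = 0.128). Control 3 lay between the groups here, with a mean deviation of -0.039 against -0.25 and -0.21 in the other controls and 0.15 to 0.18 in ZBED3-OE. None of 33 nuclear-encoded respiratory chain genes changed by limma, over all genes or adjusted over the list alone, and that list did not pass (camera, Benjamini-Hochberg adjusted p = 0.942); NDUFB8, with the smallest p, had a log2 fold change of 0.32. In that list 2 genes rose without control 3, and 1 rose and 2 fell after a GC and length trend was removed. Either count is a smaller share than that of changed genes over all tested genes in the same fit.

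Among 17 tested immediate early and heat shock genes, 4 fell (7 lower when adjusted over the list alone), with a list median of -0.18 (camera, Benjamini-Hochberg adjusted p = 1.8e-04; adjusted p = 0.138 with an estimated correlation). JUN went from 37.7 ± 5.85 to 14.3 ± 2.01 FPKM, IER3 from 61.5 ± 2.99 to 33.8 ± 3.76 FPKM, the chaperone HSP90AA1 from 341 ± 32.5 to 207 ± 16.8 FPKM and EGR1 from 4.17 ± 0.369 to 2.64 ± 0.282 FPKM. Of this list, 1 gene fell without control 2, 2 without ZBED3-OE 1, 2 without ZBED3-OE 2 and 0 without ZBED3-OE 3, and its median was -0.29 without control 3. In the same list 2 rose and 9 fell after a GC and length trend was removed, and 2 fell with no filter on low values. This list too was fixed as a check of sample quality. Of 16 matrix and fibrosis genes, 2 fell (7 lower when adjusted over the list alone) and the list median was -0.19 (camera, Benjamini-Hochberg adjusted p = 0.0099; adjusted p = 0.265 with an estimated correlation). Among these, CYR61, a matricellular protein gene, fell from 49.1 ± 2.72 to 33.1 ± 3.34 FPKM. In this list 5 genes fell without control 3, and 1 without control 2 or any of the ZBED3-OE libraries. With voom 6 fell, and after a GC and length trend was removed, 1 rose and 7 fell. Its median was -0.10 without control 2, -0.11 after quantile normalization, -0.30 with the 5 FPKM filter and -0.023 with no filter. Of 21 p53 and apoptosis genes, 4 fell, also when adjusted over the list alone, and the median was -0.13 (camera, Benjamini-Hochberg adjusted p = 0.030; adjusted p = 0.169 with an estimated correlation). GADD45A and CDKN1A, both growth arrest genes, had log2 fold changes of -0.90 and -0.62, and MCL1 and BCL2L1, which protect from apoptosis, had -0.85 and -0.55. Of the p53 list, 2 genes fell without control 2 or ZBED3-OE 2 and 1 without ZBED3-OE 3. The p53 median was -0.084 without control 2, -0.21 without control 3 and -0.077 after a GC and length trend was removed.

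In the NF-kB list 1 of 15 genes fell, LIF at -0.43 (6 lower when adjusted over the list alone), with a median of -0.20 (camera, Benjamini-Hochberg adjusted p = 0.033; adjusted p = 0.171 with an estimated correlation). The median was -0.13 with no filter on low values. In the autophagy and lysosome list 1 of 25 fell, the protease gene CTSL at -0.44, also when adjusted over the list alone, and 20 of the 25 were below 0, with a median of -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0028; adjusted p = 0.138 with an estimated correlation). Without control 3, 3 genes fell in the NF-kB list and 5 in the autophagy list; without any of the other libraries, 0 fell in either. After a GC and length trend was removed, 1 rose and 6 fell in the NF-kB list and 8 fell in the autophagy list; with voom, 4 and 2 fell. None of 33 cytosolic ribosomal protein genes changed by limma, over all genes or adjusted over the list alone, while 29 of the 33 were below 0. The list median was -0.10 (camera, Benjamini-Hochberg adjusted p = 0.014; adjusted p = 0.654 with an estimated correlation) and turned to 0.025 after quantile normalization. RPS6 had the smallest p in that list, with a log2 fold change of -0.20. Of the ribosomal genes, 3 fell without control 3, a smaller share than that of changed genes over all tested genes in that fit. Their median was -0.054 without control 1 and -0.063 with voom scaled by library totals. The NF-kB list did not pass without control 3 (camera, Benjamini-Hochberg adjusted p = 0.052) or without ZBED3-OE 3 (0.070), and the ribosomal list did not pass without control 1 (0.298) or without ZBED3-OE 2 (0.170). With low values filtered at 5 FPKM in 3 samples, the NF-kB, p53 and ribosomal lists had camera adjusted p (Benjamini-Hochberg) of 0.355, 0.052 and 0.111. These lists had 0.059, 0.076 and 0.087 after a GC and length trend was removed, and 0.0501 each among protein-coding genes alone (camera, Benjamini-Hochberg adjusted p). The ribosomal list did not pass after quantile normalization (camera, Benjamini-Hochberg adjusted p = 0.432) or by fry (Benjamini-Hochberg adjusted p = 0.279).

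Lists that did not pass included the Wnt list, in which 1 of 19 tested genes rose, also when adjusted over the list alone: WNT5A went from 13.5 ± 1.08 to 19.3 ± 1.23 FPKM (camera, Benjamini-Hochberg adjusted p = 0.973 for the list). WNT5A passed with control 3 left out, where 1 other gene of the list fell, but not with any of the other libraries left out; after a GC and length trend was removed, 3 rose and 2 fell. CTNNB1, the beta-catenin gene, was at 17.8 ± 1.43 and 17.5 ± 0.853 FPKM. None of 34 cell cycle genes passed limma, over all genes or adjusted over the list alone. CDC20 at -0.40 had the smallest p (camera, Benjamini-Hochberg adjusted p = 0.478 for the list). Without control 3, 2 fell, and after a GC and length trend was removed, 4 rose and 2 fell. Calls over all genes rose to 1619 of 13402 and 2243 of 13647 in these fits, so such counts do not mark out the list. None of 26 genes of the unfolded protein response and integrated stress passed either, over all genes or adjusted over the list alone, with PSAT1 at 0.46 having the smallest p (camera, Benjamini-Hochberg adjusted p = 0.074). Of these 26, 2 rose and 6 fell without control 3, and 4 rose and 8 fell after a GC and length trend was removed. That list passed as lower with no filter on low values (camera, Benjamini-Hochberg adjusted p = 0.010) and by fry (Benjamini-Hochberg adjusted p = 0.042). Of 20 oxidative stress genes, 1 fell, the ferritin light chain FTL at -0.35 (3 lower when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.150, and 0.046 by fry). Without control 3, 1 oxidative stress gene rose and 4 fell, and without any of the other libraries none passed. With voom 4 fell, and after a GC and length trend was removed, 1 rose and 3 fell. FTL was at -0.16 after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.092). Only 2 of 21 genes for lipoprotein assembly and bile acids reached the filter, and that list was not tested.

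Marker genes showed little hepatocyte-specific mRNA in these cells. Of 28 hepatocyte markers, 25 were under 1 FPKM in every library, and albumin (ALB) was listed at 0 in the controls and at a mean of 0.0064 FPKM in ZBED3-OE. The other 3 were tested: CPS1, the first enzyme of the urea cycle, rose from 71.4 ± 7.95 to 113 ± 5.14 FPKM, while the transcription factor genes HNF4A, at 1.47 ± 0.350 and 1.69 ± 0.137 FPKM, and CEBPA, at 1.47 ± 0.769 and 1.34 ± 0.410 FPKM, did not pass. CPS1 was also the 1 that passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.141 for the list, and 0.023 by fry). Of 13 cholangiocyte and progenitor markers, 8 were tested and none passed over all genes (1 higher and 1 lower when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.876), with SOX9 at 2.004 ± 0.319 and 0.995 ± 0.117 FPKM. Of 3 tested stellate and fibroblast markers, VIM fell from 95.5 ± 7.35 to 64.9 ± 0.925 FPKM (1 higher and 1 lower when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.973). Neither CPS1 nor VIM passed without control 2 or any of the ZBED3-OE libraries. Without control 3, 1 cholangiocyte and progenitor marker rose and 2 fell, and 1 stellate and fibroblast marker rose beside the fall of VIM. After a GC and length trend was removed, 2 of the former rose and 1 fell, and 1 of the latter rose and 1 fell. All 11 endothelial and all 13 macrophage and leukocyte markers were under 1 FPKM in every library.

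**Figure D2:**
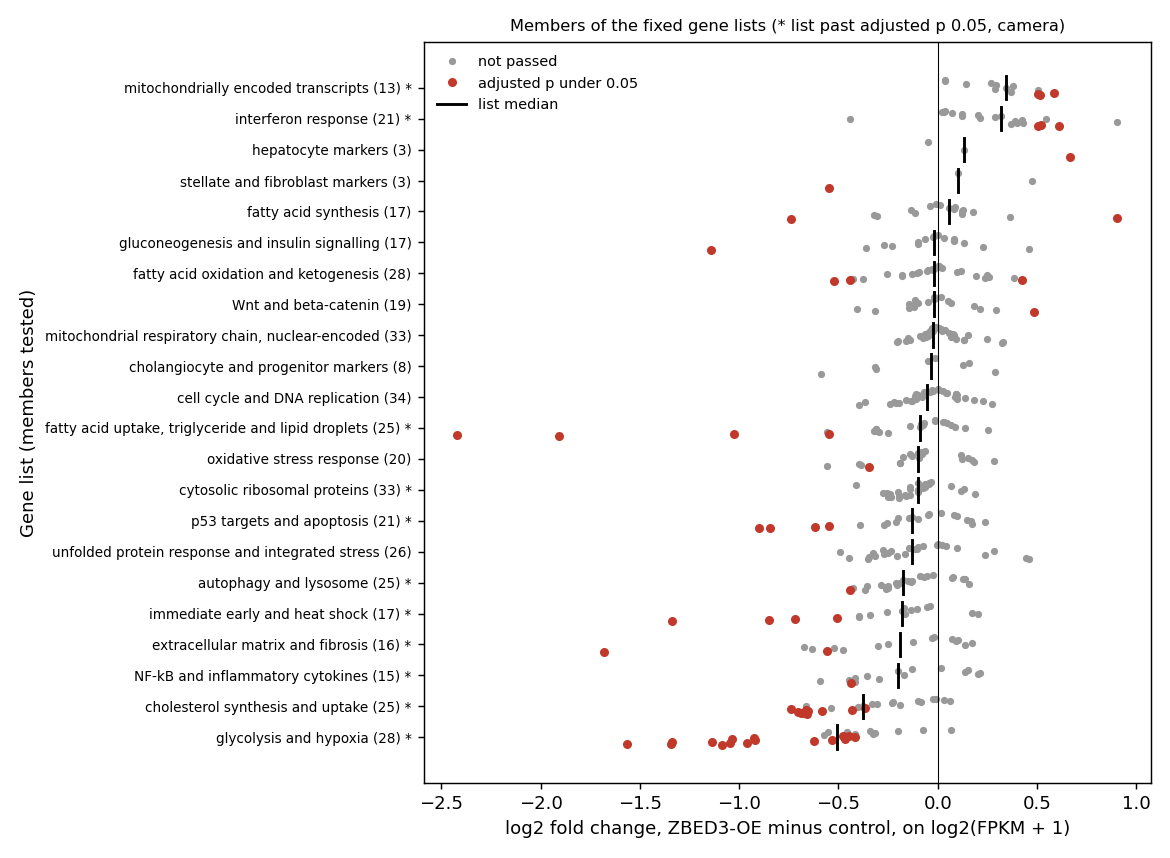
Log2 fold change (ZBED3-OE minus control, on log2(FPKM + 1)) of each tested member of the 22 tested lists; each point is a gene, red where its limma adjusted p was under 0.05, black bars are list medians, and an asterisk marks the 11 lists past an adjusted p of 0.05 by camera. Medians run from -0.50 for glycolysis and hypoxia to 0.35 for mitochondrially encoded transcripts, and the ribosomal median changes sign after quantile normalization.

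Outside the lists, the genes that the naming rule ranked highest after ZBED3 were the chloride channel gene ANO2 (1.11 on the log2 scale, from 3.24 ± 0.142 to 8.18 ± 0.339 FPKM), the synaptic vesicle protein gene SV2B (1.04) and the protease inhibitor gene SPINK5 (1.03, from 21.7 ± 1.68 to 45.3 ± 3.03 FPKM). TRIM31, TCN1, ZXDB, FAAH2 and ALPI followed, between 1.00 and 0.91. ALPI, ZXDB, HSP90AA1, FTL, the mitochondrial genes and ribosomal protein genes have near-identical copies or pseudogenes, and how shared reads were counted is not given in the sources used here, so their values are uncertain. Large decreases outside the lists were found for TMEM158 (-1.71), the keratin KRT15 (-1.50), RNF223 (-1.37), SERTAD1 (-1.37) and the AP-1 subunit FOSL1 (-1.36, from 50.7 ± 6.46 to 19.2 ± 3.96 FPKM). An antisense gene, ZBED3-AS1, was listed at 0.140 FPKM in control and 0.216 FPKM in ZBED3-OE, and reads of overlapping genes on opposite strands cannot be separated without strand.

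Of 59 named genes, 54 passed the threshold, and 17 of these, among them ZBED3, ANO2, SPINK5, ACSS2, PLIN2, ANGPTL4, HILPDA, PFKFB4, ADM, EGLN3, ALDOC, IGFBP1 and GADD45A, also had an adjusted p under 0.05 in every other limma or voom fit that tested them. Of these, ACSS2 and GADD45A changed by less than the alternative log2 fold minimum of 1. The other 37 did not pass without at least 1 of the libraries. The count of 553 genes depended on each library, with 245 genes without control 1, 54 without control 2, 1619 without control 3, 141 without ZBED3-OE 1, 48 without ZBED3-OE 2 and 29 without ZBED3-OE 3. It came to 128 with no filter on low values, 999 with voom on recovered reads and 2243 after a GC and length trend was removed from each library.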

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

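Voom with library totals, the filter of 10 reads, the protein-coding set and the GC and length correction were chosen after seeing the data. ZBED3 rose in every setting, by 1.20 to 1.47 on the log2 scale. The main counts were 553 genes changed, 216 higher and 337 lower. With no filter on low values they were 128, 44 and 84, with 33763 genes tested. Voom on recovered reads gave 999, 393 and 606, and with library totals 989 genes changed, 528 of them higher. The GC and length correction gave 2243, 972 and 1271, and the protein-coding set 517 lower genes. A log2 fold minimum of 1 left 76, 36 and 40. The fold minimum acts by construction and the missing filter adds tested genes; the cause of the other shifts was not tested. With replicate number as a block, the counts were 278, 107 and 171. Deviations of same-numbered samples correlated at 0.228, -0.093 and -0.068. Control 1 and ZBED3-OE 1 were each other's closest partner, while the samples numbered 2 and 3 were not. Pairing by number is therefore not shown, but these 3 values cannot exclude it.

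With each library left out, changed genes ranged from 29 to 1619, higher genes from 10 to 550 and lower genes from 19 to 1069. Without control 1 there were 245 changed genes, without control 2 there were 54, without control 3 there were 1619, without ZBED3-OE 1 there were 141, without ZBED3-OE 2 there were 48 and without ZBED3-OE 3 there were 29. Fewer samples lower the power by construction. The cause of the increase without control 3 was not tested. Spearman correlations of deviations with GC content across genes were 0.602, 0.401 and -0.523 in controls 1 to 3. They were 0.221, -0.563 and -0.190 in ZBED3-OE 1 to 3. With control 3 left out, the remaining controls exceeded every ZBED3-OE library, so a GC trend cannot be told apart from group in that fit. Lists passing numbered 10 to 11 over these fits, 8 to 11 in the other fits with camera at the preset correlation, 1 with an estimated correlation and 13 by fry. The ribosomal list reversed under quantile normalization, with a median of 0.025, and the cause was not tested. Over the other list results, 430 held, 25 were lost and 4 were gained; over named genes, 873 held, 188 were lost and 23 were gained. Fits with edgeR and DESeq2, including their scalings and filters, were foreseen but not run, as the deposited values are FPKM. The recovered reads would have allowed such fits, and only voom was run on them.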

Other observations

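The gene families described first and the tests of PPAR targets and of short RNA genes were chosen after values had been seen. The panels of oxygen-response and MAPK output genes were chosen after the list results, but before values of their members were looked at. Of 11 tested keratin genes, 5 fell by limma and none rose, with a median log2 fold change of -0.45. It stayed between -0.52 and -0.34 with a common median, quantile normalization and voom with either scaling. The epithelial pair KRT8 and KRT18 went from 205 ± 30.3 to 132 ± 9.31 FPKM and from 227 ± 18.3 to 158 ± 16.4 FPKM (SD, n = 3). Their limma adjusted p (Benjamini-Hochberg) were 0.0392 and 0.0398, near the threshold. Fits with a library left out were not examined for this pair. KRT16 went from 11.2 ± 1.64 to 5.88 ± 0.597 FPKM. Of 3 tested metallothionein genes, whose products bind zinc and copper, 2 fell, with a median of -0.72. As these families were picked for their values, no test of a family as a set is given. MT2A went from 221 ± 15.7 to 112 ± 13.7 FPKM and MT1X from 5.18 ± 0.492 to 2.76 ± 0.143 FPKM.

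Of 4 tested alkaline phosphatase genes, 3 rose, with a median of 0.59. ALPI had 184 ± 30.7 and 345 ± 41.8 FPKM and ALPL, the liver, bone and kidney form, 83.5 ± 11.4 and 121 ± 7.04 FPKM; reads of ALPI, ALPP and ALPG are hard to separate. Among 5 urea cycle genes, ASS1 rose from 326 ± 35.0 to 505 ± 17.1 FPKM together with CPS1, while ASL, ARG2 and SLC25A15 did not pass. FAAH2 (57286706 to 57489196) and ZXDB (57591652 to 57597545) are neighbours on chromosome X and rose by 0.95 each. The flanking SPIN2B and ZXDA had log2 fold changes of 0.032 and 0.42, with limma adjusted p (Benjamini-Hochberg) of 0.874 and 0.069. FAAH2 and ZXDB each did not pass without at least 1 of the libraries, and no test compared them with the flanking genes.

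Chance division of the samples was examined by refitting all 10 splits of the 6 samples into 3 and 3. The real split gave 553 changed genes, 216 higher, 337 lower and 11 lists, and the highest of the other splits gave 1, 1, 1 and 6. For each of these, 1 of the 10 splits gave a result as large, and 10 splits are too few for a share under 0.05.

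For the lower glycolysis and hypoxia genes, GC content and gene length were weighed because deviations of single libraries followed GC, with Spearman correlations across genes of 0.602 in control 1, -0.523 in control 3 and -0.563 in ZBED3-OE 2. After that trend was removed the list median was -0.47 (95% bootstrap interval over members -0.88 to -0.38), with 23 of 28 members lower. That trend therefore does not account for the whole pattern. With reads scaled by library totals the list median was -0.54 (-0.92 to -0.43). Voom with these totals in place of median-of-ratios scaling moved the median over tested genes only from -0.010 to 0.033. Such a small shift cannot decide whether scaling plays a part. The intervals treat members as independent, whereas their estimated correlation was 0.414. A panel of 20 other oxygen-response genes, none in the lists, had a median of -0.59 (-0.65 to -0.42), with all 20 below 0 and 11 passing (camera of limma, Benjamini-Hochberg adjusted p = 9.4e-16 over 3 panels; adjusted p = 0.064 with an estimated correlation). The panel extends the pattern to more oxygen-response genes. As the list already held hypoxia genes such as EGLN3 and ADM, seen to fall beforehand, the panel is no independent test of a cause. A lower oxygen-response programme in ZBED3-OE stays a hypothesis. HIF1A and EPAS1 mRNA were at 33.0 ± 5.17 and 39.1 ± 3.08 FPKM in control and 34.2 ± 1.90 and 39.2 ± 3.23 FPKM in ZBED3-OE. Cell density or oxygen in the dishes, which the labels do not give, stays open.

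The fall of PLIN2, ANGPTL4 and HILPDA, which are known PPAR targets, could come from lower PPAR target expression in general. A panel of 13 PPAR targets of fatty acid oxidation had a median of -0.055 (95% bootstrap interval -0.18 to 0.00046), and 9 of the 13 were below 0, of which 2 passed (camera of limma, Benjamini-Hochberg adjusted p = 0.053; adjusted p = 0.110 with an estimated correlation). All but ACSL1 belong to the fatty acid oxidation list. The largest falls were -0.52 for SLC25A20 and -0.44 for ACAA2, against -1.03 for HILPDA, the smallest fall of the 3 genes. The 13 targets of the panel thus fell by less than these 3 genes. The panel was drawn after the oxidation list was seen not to pass, so it is no independent test of PPAR targets in general. A smaller or partial fall stays open. ANGPTL4 and HILPDA are also known to respond to hypoxia, and a different lipid content of the cells was not measured, so these stay open too. Whether PLIN2 fell with the oxygen-response genes was not tested. The lower lipid uptake and droplet list is therefore not shown to be separate from the lower glycolysis and hypoxia list. For FOSL1 and JUN, lower MAPK output may contribute: a panel of 13 other MAPK output genes had a median of -0.28 (-0.50 to -0.052), with 2 passing as lower (camera of limma, Benjamini-Hochberg adjusted p = 3.9e-04; adjusted p = 0.074 with an estimated correlation). That median was -0.16 without control 2 and -0.20 without ZBED3-OE 3, so it rests in part on those libraries. JUN belongs to a list fixed as a check of sample quality, and a difference in sample quality between the groups stays open.

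Non-coding genes made up more of the higher than of the lower calls: 56 of 1408 long non-coding and other genes were higher and 16 lower, against 128 higher and 292 lower of 10834 coding genes, and 18 of 560 short or structural RNA genes were higher and 9 lower. Of those 18, 2 had 10 or more reads in every ZBED3-OE library and 2 passed with voom. Of all 560 tested short or structural RNA genes only 57 had as many reads, so whether few reads account for the short RNA calls stays open. Long non-coding genes had a median log2 fold change above that of coding genes of like read number by 0.15 (95% bootstrap interval 0.085 to 0.207). Leaving out bins of read number with under 20 coding genes gave 0.13, with 7 of 7 bins above 0. A general shift of long non-coding transcripts may underlie these values, and a difference in nuclear or unspliced RNA between the libraries was not tested. The difference was computed without the GC and length correction, and its interval resamples genes, not samples. Median gene length was 939 bases in long non-coding and other genes and 5124 in coding genes. A GC or length trend therefore stays open.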
